A study of Mus musculus with 27 samples.

How the data were processed

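The series measured the 3' ends of polyadenylated RNA in the intestine of C57BL/6 mice, an inbred laboratory strain, that drank water or 15% ethanol for 8 weeks. Libraries were made with the QuantSeq 3' mRNA-Seq kit, which reads 1 tag near the 3' end of a transcript, so that counts need no correction for transcript length. Colon and jejunum (the middle part of the small intestine) were each sampled as whole tissue and as organoids, 3-dimensional cultures grown from the epithelial stem cells of the crypts. The 27 libraries formed 8 groups, taken from the sample titles and source names: 2 control and 2 ethanol colon organoid libraries, 4 and 4 jejunum organoid libraries, 4 and 4 colon tissue libraries, and 3 control and 4 ethanol jejunum tissue libraries. The labels give the libraries of a group separate donor numbers, and the same numbers recur in every group, also under both treatments. No label gives a sequencing batch or date.

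The authors deposited raw read counts per gene, in whole numbers, for all 27 libraries. Per the submitters' processing notes, Trimmomatic 0.32, BWA and HTSeq were among the tools used upstream of the counts, limma and edgeR were used after them, and the genome build was mm10; which settings were used, and whether reads were counted by strand, is not given in the sources used here. Overlapping genes on opposite strands, and gene copies with near-identical 3' ends, may therefore share reads. The authors also deposited a normalized table with 13560 genes, whose values fall on no standard unit and are treated here as a score on a log-like scale; its values run from -0.315 to 8.93 and 21.3% of its cells are blank. The ranks of its values within each library were those of the counts. It was used for 1 alternative only, with limma, on the genes without a blank in the libraries compared (6931 in organoids, 8217 in tissue).

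The count table held 23420 genes by symbol and no blank or summary entry. Genes of the mitochondrial chromosome were not analysed here. Of the symbols, 21777 (93%) were found in the GENCODE vM21 annotation of GRCm38, the assembly also called mm10, and coordinates are given for those, counted from 1. Symbols are printed as the table gives them. Total counts per library ran from 1337068 to 16312562. A single entry, Rn45s (45S pre-ribosomal RNA), took up to 84.3% of a library, so that the counts outside Rn45s ran from 684906 to 7606668. The share of Rn45s was compared between ethanol and control libraries with a two-sided exact permutation test. Replicates were compared first: in all 35 pairs of libraries of the same group the counts differed by more than sampling noise (chi-square over genes with at least 20 counts, 3.32 to 209 per degree of freedom), so that no library was counted as a repeat of another.

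Each comparison was tested with edgeR 4.0.16 (in R 4.3.3): TMM normalization on all genes, filterByExpr by group, the robust quasi-likelihood fit and its two-sided F-test, with Benjamini-Hochberg adjustment over the genes kept. A gene was called at an adjusted p under 0.05. The 12 organoid libraries were fitted together and the 15 tissue libraries together, with 1 coefficient per group, for the ethanol effect in each segment, the difference of the ethanol effect between segments, and colon against jejunum in controls. All 27 libraries entered 1 fit for organoids against tissue. Values per gene are CPM scaled by the TMM factors, given as mean ± SD over the libraries of a group, and fold changes are log2 ± standard error of the fit. Where all libraries of a group held no count of a gene, the fold is given as a lower bound against a floor of 3 counts over the group. The other group enters this bound at its measured value, so that its own error and spread are not covered. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Counts of genes with group ranges apart are set against the share that chance gives: 33.3% for 2 against 2, 2.86% for 4 against 4 and 5.71% for 3 against 4 libraries.

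Gene lists, 53 in all, were fixed before the data were examined: intestinal cell types and stem cell programmes, junctions, mucus, ethanol, retinoid, lipid and xenobiotic metabolism, stress and immune programmes, and markers of cell types that tissue could carry along. Lists with at least 5 tested members (48 in organoids, 50 in tissue) were tested with limma's camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation, and fry, were alternatives. Beside the calls over all genes, members are counted as adjusted over the list alone. The rule for naming genes was also fixed before the data were examined. In each ethanol comparison it took the 6 highest and the 6 lowest fold changes among called genes with group ranges apart and a mean of at least 5 CPM (with fewer than 12 calls, the 6 smallest p-values in each direction, as values), up to 4 called members of each list in each direction, and always Lgr5, Chga, Tjp1, Ocln, Cldn1, Cldn3, Adh1, Aldh1a1 and Muc2. Comparisons of segments and preparations took the 4 largest changes each way and up to 3 called members of each list in each direction. Predicted genes were skipped among the largest changes. The rule named 160 genes in colon organoids, of which the text prints a part; some genes that the rule named are not reported here. Cldn1 was not kept by the filter in organoids.

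The tests were checked on simulated counts with the real library sizes and the mean of each gene over all libraries of its fit. The 200 changed genes were drawn among those with a mean of at least 5 CPM, so the rates do not cover genes below it. Numbers of genes in parentheses are all genes tested. In the ethanol comparisons edgeR recovered 35% of 4-fold changes in colon organoids (12033 genes), 81% in jejunum organoids (12102 genes), 91% in colon tissue (13143 genes) and 75% in jejunum tissue (13183 genes); of 2-fold changes it recovered 8%, 25%, 26% and 10%. Between 0 and 6 unchanged genes were called. That simulation gave all libraries of a fit a common spread, so it could not show false calls that come from unequal spread. A further simulation, chosen after the results were seen, therefore gave each colon organoid group its own spread and no ethanol effect (20 sets), and its counts are printed beside the measured ones.

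Alternatives fixed before the data were examined were DESeq2's size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, the authors' normalized values, the donor number as a block, a fit of all 27 libraries, a fit of only the groups compared, and leaving out each library in turn. The donor numbers were not used as pairs in the main tests. Alternatives added after the data were seen were: Rn45s left out, limma-voom with a spread per kind of sample, colon tissue without the 3 libraries in which Hoxb13, a gene of the distal colon, exceeded 5 CPM or with a term for it, and a term for the Rn45s share in tissue. The kinds of sample were the combinations of segment and preparation, so control and ethanol libraries of a kind shared a common spread. Correlations of fold changes between organoids and tissue are across genes, which are not independent replicates, and carry no p-value. Plots were drawn with matplotlib 3.10.9 (Python 3.11.15).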

Results

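RNA was counted by 3' tag sequencing in 27 libraries from mice that drank water or 15% ethanol for 8 weeks. The colon and the jejunum were each studied as whole tissue and as organoids, cultures grown from epithelial stem cells. According to the title of the series, the study asks whether alcohol makes the colon more permeable and changes the fate of stem cells in colon organoids. Depth differed widely between the groups. Control colon organoids (n = 2) had total counts of 1337068 to 2806471 and ethanol colon organoids (n = 2) of 2601537 to 4595625. Totals were 3934204 to 7090123 in the 8 jejunum organoid libraries and 4598706 to 8424316 in the 8 colon tissue libraries. Jejunum tissue had 4370319 to 7116178 in controls (n = 3) and 8643722 to 16312562 with ethanol (n = 4). Much of that was Rn45s, the precursor of ribosomal RNA, which took 76.3 to 84.3% of the counts of control jejunum tissue and 53.4 to 80.8% of those of ethanol jejunum tissue. That left 684906 to 1510057 and 2099739 to 7606668 counts for all other genes. In neither segment, as tissue or organoids, did its share differ between ethanol and control libraries beyond chance (two-sided exact permutation p from 0.114 to 0.743, with 2 against 2 libraries the smallest possible p is 0.333).

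**Figure D1:**
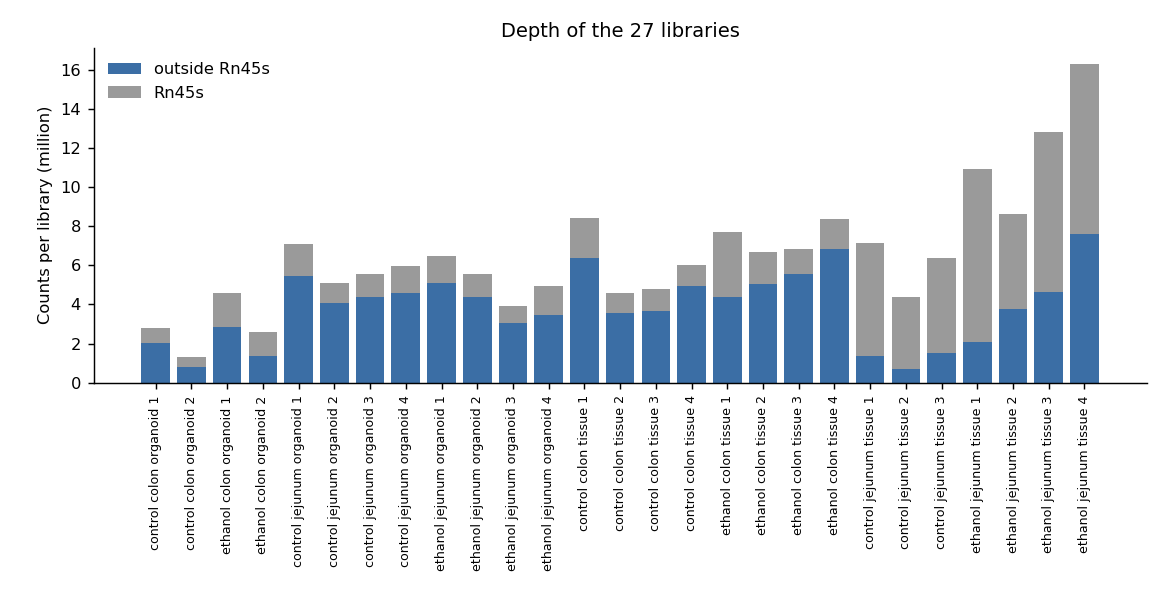
Total counts of each of the 27 libraries, split into Rn45s and all other genes. Control jejunum tissue kept 684906 to 1510057 counts outside Rn45s, and control colon organoids 818240 to 2036195.

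The replicates of the groups differed in spread as well. The biological coefficient of variation of genes with a mean of at least 5 counts was 1.19 in control colon organoids and 0.513 in ethanol colon organoids. It was 0.189 and 0.146 in control and ethanol jejunum organoids and 0.295 to 0.371 in the tissue groups. Between genes with a mean of at least 500 counts it was 0.373 and 0.264 in the colon organoid groups. The 2 control colon organoid libraries had a Spearman correlation of 0.676 across genes and the 2 ethanol libraries of 0.877, while pairs of jejunum organoid libraries of a group had 0.979 to 0.992.

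In colon organoids, Car1, a carbonic anhydrase of surface colonocytes (chromosome 3, 14766216 to 14808368, GRCm38), was called higher in the cultures from ethanol-fed mice. It stood at 5920 ± 1668 CPM against 595 ± 9.73 CPM in controls (SD, n = 2 and 2), a log2 fold change of 3.32 ± 0.32 (edgeR adjusted p = 0.000153). Guca2a, which encodes the peptide guanylin (chromosome 4, 119637704 to 119639471), was higher by 4.31 ± 0.53 (943 against 48.1 CPM) and the transmembrane mucin Muc13 by 3.33 ± 0.32 (1411 against 141 CPM). Of the junction genes, the claudin Cldn7 (chromosome 11, 69964779 to 69967885) was higher by 2.54 ± 0.20, at 2141 ± 303 against 369 ± 28.5 CPM (edgeR adjusted p = 7.18e-05). In the opposite direction, Rnf43, an inhibitor of Wnt receptors that Wnt signalling itself induces, was lower by a log2 fold change of -2.88 ± 0.34 (8.48 against 62.9 CPM, edgeR adjusted p = 0.000414). In all, edgeR called 2260 of 12922 genes, 1638 higher and 622 lower with ethanol. The control libraries also held fewer detected genes, 11780 and 9951 against 15383 and 13542, although control library 1 had more counts outside Rn45s than ethanol library 2 (2036195 against 1345224). Their Rn45s share was 33.1 ± 8.03% against 43.2 ± 7.19%. Whether a property of the libraries other than depth or spread lies behind the excess of higher genes was not tested. The number of calls cannot be separated from the spread of the libraries. Counts simulated with no ethanol effect, with each colon organoid group keeping its own spread, gave a median of 2394 calls (2213 to 2521 in 20 sets), with medians of 1726 higher and 624.5 lower. In these sets 68.4 to 75.4% of the calls were higher (median 73.9%), against 72.5% measured. The spread within the groups may thus account for the excess of higher genes as well. Fitted alone, the 4 colon organoid libraries gave 0 calls with edgeR among 10712 genes (829 at an unadjusted p under 0.05, where chance gives 536, smallest adjusted p 0.326), but that fit has 2 residual degrees of freedom instead of 8 and so says little.

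**Figure D2:**
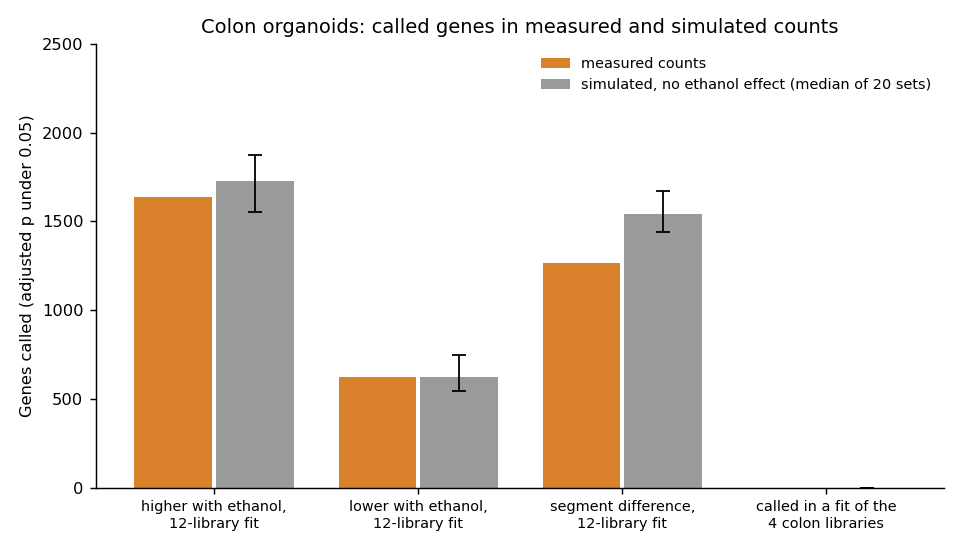
Numbers of genes called by edgeR between ethanol and control colon organoids, as measured and in 20 sets of counts simulated with no ethanol effect. The measured 2260 calls lie within the simulated range of 2213 to 2521.

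The number of calls also moved with the libraries and the tool. It was 5864 without control library 1, 4250 without control library 2 and 1504 without ethanol library 2. DESeq2 called 3074 genes, limma-voom 2552, and limma-voom with a spread per kind of sample 5: Spint2, Car1, Neurl1b, Fam83b and Cldn7, all higher (limma adjusted p = 0.0359 to 0.0388), which were picked out after their values were seen. Group ranges were apart in 40.6% of all genes tested, where chance gives 33.3%. Of the called genes, 580 had no count in either control library and 26 none in either ethanol library. For such genes the size of the fold rests on the floor of the group without a count. The genes with the highest fitted fold changes were of this kind: Apob, the apolipoprotein of chylomicrons (chromosome 12, 7977648 to 8016835), was at 71.8 ± 12.8 CPM with ethanol and at least 106-fold higher than in controls. Fam83b (chromosome 9, 76490054 to 76567116) was at least 108-fold higher and Cacna2d1 at least 71.5-fold. Btnl1, a butyrophilin-like gene of gut epithelium (chromosome 17, 34377132 to 34386028), was higher at least 56.1-fold, Il22ra1, a subunit of the IL-22 receptor, at least 47.3-fold, and Dfna5 at least 49.4-fold. The lowest were Rfx4 (at least 42.2-fold lower), Pot1b (27.3-fold), Lhx9 (23.2-fold), Piezo2 (23.6-fold), Otog (21.9-fold) and Mei1 (17.4-fold), each without a count in the ethanol libraries. In controls Rfx4 was at 30.3 ± 32.2, Otog at 16.6 ± 19.9 and Mei1 at 12.8 ± 14.6 CPM, with an SD above the mean. For Pot1b, Lhx9 and Piezo2 the SD was below the mean.

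By group, the smallest camera p belonged to xenobiotic metabolism. Of 25 tested cytochromes, carboxylesterases and transferases, 17 were higher and 0 lower (21 and 0 when adjusted over the list alone), with a median log2 fold change of 3.77 (2.78 with genes absent from a group at their bound). Cyp2c65 was at 59.1 ± 3.43 against 8.31 ± 2.13 CPM and Ces2c at 262 ± 7.42 against 15.9 ± 14 CPM. Camera gave an adjusted p = 1.42e-13 for this list, and an adjusted p = 0.163 with an estimated correlation. Of 27 small intestinal enterocyte markers, 10 were higher and 1 lower (11 and 1 over the list alone; camera adjusted p = 6.78e-05, adjusted p = 0.363 with an estimated correlation). Among them was Apoa1 at 42.2 ± 8.73 against 5.12 ± 1.42 CPM, while Gata4, a transcription factor of the proximal intestine, was lower. Of 20 colonocyte markers, 7 were higher and 0 lower (9 and 0 over the list alone), with a median of 1.46 (camera adjusted p = 0.0018, adjusted p = 0.163 with an estimated correlation). Among them was Lypd8, which keeps bacteria from the colon surface, higher by 2.42 ± 0.57. In the bile acid list, 3 of 8 genes were higher (4 over the list alone; median 4.79, 3.72 at the bound; camera adjusted p = 0.0103, adjusted p = 0.363 with an estimated correlation). They were both subunits of the basolateral bile acid exporter, Slc51a (98.8 ± 28.4 against 2.72 ± 3.85 CPM) and Slc51b (at least 52.4-fold), and the bile acid receptor Nr1h4. Of 24 genes of fatty acid oxidation, 10 were higher and 1 lower (13 and 1 over the list alone; camera adjusted p = 0.00498, adjusted p = 0.503 with an estimated correlation). They included the dehydrogenases Acadm (2.66 ± 0.31) and Hadha (1.82 ± 0.29), and Ucp2 was the lower one. The monoamine oxidase Maoa, at 1688 ± 310 against 282 ± 61.5 CPM, was 1 of 3 higher genes among 7 of serotonin and neuropeptide signalling (4 over the list alone, camera adjusted p = 0.0238, adjusted p = 0.363 with an estimated correlation).

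The lists of stem cells and of regenerating epithelium had negative medians and passed camera with the preset correlation, with few of their genes called. Of 23 stem cell genes, 4 were lower and 1 higher (5 and 2 over the list alone, median -0.325, camera adjusted p = 0.0238, adjusted p = 0.363 with an estimated correlation). The 4 were Rnf43, the Wnt target Axin2 (-1.69 ± 0.35), Aqp4 and Lrig1, while Tnfrsf19 was higher. Lgr5, the receptor that marks crypt stem cells (chromosome 10, 115450311 to 115587780), was not called: 6.92 ± 7.58 against 14.5 ± 2.27 CPM, a log2 fold change of -0.99 ± 0.73 (edgeR adjusted p = 0.395). In the list of fetal-like and regenerative epithelium, 3 of 16 genes were lower and 0 higher (the same numbers over the list alone, median -0.81, camera adjusted p = 0.0062, adjusted p = 0.363 with an estimated correlation). They included Krt7, a keratin of simple duct-like epithelia, at 495 ± 20.8 against 1212 ± 454 CPM, and Anxa1 (-1.35 ± 0.35). Proliferation genes did not pass as a list (camera adjusted p = 0.0525), with 4 of 26 lower, among them Mcm5 and Cdc20, and 1 higher. Of 31 ribosomal protein genes, 6 were lower and 1 higher (the same over the list alone, camera adjusted p = 0.0062, adjusted p = 0.741 with an estimated correlation). In the list of keratins and the epithelial cytoskeleton, 8 of 18 were higher and 2 lower (10 and 3 over the list alone, camera adjusted p = 0.0245, adjusted p = 0.593 with an estimated correlation). The higher ones included the brush border genes Cdhr5 (879 ± 24.9 against 81.9 ± 3.24 CPM), Eps8 and Myo7b, and the lower ones were Krt7 and Krt18. Some markers of immune cells were also higher in these libraries: of 10 macrophage and dendritic cell markers 2 were higher with ethanol and 0 lower (3 and 0 over the list alone), although the list did not pass (median 1.5, camera adjusted p = 0.231). They were Csf1r, the receptor of a macrophage growth factor, at 156 ± 149 against 18.9 ± 12.3 CPM, and Itgam, at least 19.3-fold higher. Ctss, a protease of antigen-presenting cells, was at 184 ± 83.9 against 21.2 ± 30 CPM. B and plasma cell markers leaned the other way, with 0 of 8 positive and 0 called (median -1.67, -0.82 at the bound, camera adjusted p = 0.148). Of the 10 lists called in colon organoids, 1, that of xenobiotic genes, passed camera in all 4 fits that left out 1 library. The other 9 did not pass without control library 1 (adjusted p from 0.0604 to 0.804) and 4 not without ethanol library 2 (0.0739 to 0.301). The stem cell list failed also without control library 2 (0.168), and this list and the bile acid list failed without ethanol library 1 (0.184 and 0.162).

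**Figure D3:**
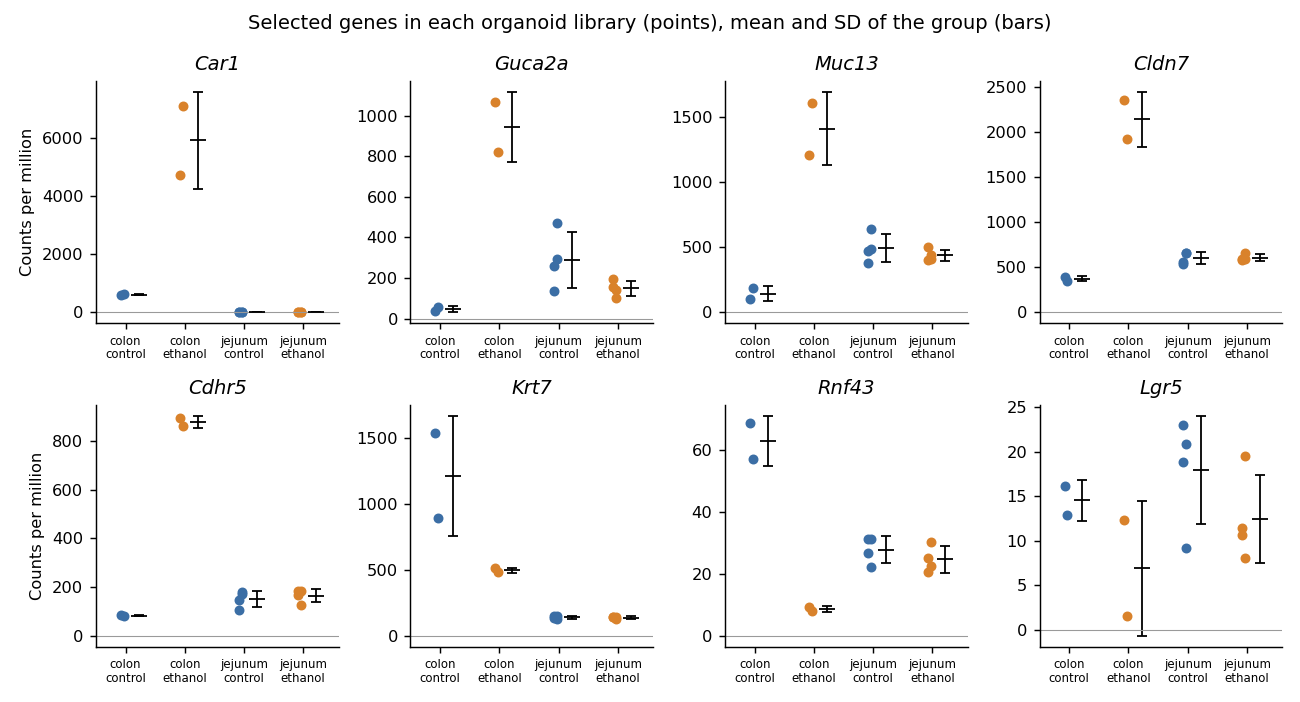
CPM of 8 genes in each of the 12 organoid libraries, with the mean and SD of each group; colon groups have 2 libraries and jejunum groups 4. In colon organoids Car1 stood at 595 CPM in controls and 5920 CPM with ethanol, and Rnf43 at 62.9 and 8.48 CPM.

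Junction, mucus and ethanol genes were measured in the same libraries because the study concerns permeability. Of 28 tight junction genes, 5 were higher in ethanol colon organoids and 0 lower (6 and 0 over the list alone), but the list did not pass (camera adjusted p = 0.208). Beside Cldn7 these included Cldn15 (4.47 ± 0.44), Cldn3 (1.61 ± 0.26, 677 ± 227 against 221 ± 53.9 CPM) and occludin, Ocln (0.77 ± 0.24, 76.9 ± 11.5 against 45.1 ± 8.33 CPM, edgeR adjusted p = 0.0449). Tjp1, which encodes the scaffold protein ZO-1, was at 137 ± 0.913 against 120 ± 104 CPM (0.18 ± 0.47, edgeR adjusted p = 0.845). The secreted mucin Muc2 was at 836 ± 270 against 202 ± 237 CPM (edgeR adjusted p = 0.0884) and was not called, whereas the goblet cell products Tff3 (2.30 ± 0.45) and Zg16 (2.43 ± 0.56) were. Neither the goblet cell list (camera adjusted p = 0.0653) nor that of mucins and mucus glycosylation (camera adjusted p = 0.148) passed. Of the 20 genes of ethanol and aldehyde metabolism, 3 were higher and 1 lower; the alcohol dehydrogenase Adh1 (-1.72 ± 0.85, adjusted p = 0.189 with edgeR) and the retinal dehydrogenase Aldh1a1 (0.69 ± 0.82, adjusted p = 0.625) were not called. Chga, a granule protein of enteroendocrine cells, was at 155 ± 49.1 against 201 ± 219 CPM (edgeR adjusted p = 0.74).

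In jejunum organoids (n = 4 and 4), edgeR called 0 of 12922 genes between ethanol and control. At an unadjusted p under 0.05 there were 146 genes where chance gives 646, but this fit shares its spread with the more variable colon organoids. A fit of the jejunum organoid groups alone also gave 0 calls. It had 755 of 10608 genes at an unadjusted p under 0.05, where chance gives 530 (smallest edgeR adjusted p 0.0781). In the shared set limma-voom called 0 and DESeq2 1. The smallest p-values belonged to Dmbt1, a secreted defence protein, at 409 ± 75.6 CPM with ethanol against 187 ± 63.6 CPM (1.13 ± 0.26), and to Parp3 (1.41 ± 0.33), followed in the same direction by Msln, Dgat1, Tff1 and Anxa1. In the other direction they belonged to Car8 (34.1 ± 5.6 against 69.5 ± 13.3 CPM, -1.03 ± 0.28), Slc28a2, Slc5a8, Ereg, Phldb2 and Xlr3a; all had an edgeR adjusted p of 1. Group ranges were apart in 3.43% of genes (chance gives 2.86%). Lgr5 was at 12.4 ± 4.94 against 18 ± 6.08 CPM, and Tjp1 (0.01 ± 0.33), Cldn3 (-0.06 ± 0.18) and Ocln (-0.16 ± 0.17) lay close to 0. Adh1 (0.48 ± 0.53), Aldh1a1 (0.92 ± 0.58), Muc2 (0.62 ± 0.53) and Chga (-0.13 ± 0.44) were not called either.

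Some lists of the jejunum organoids nevertheless leaned 1 way by small amounts (adjusted p in parentheses from camera with the preset correlation). Of 29 genes of oxidative stress and NRF2 targets 28 had a positive fold change, with a median log2 of 0.31 (adjusted p = 2.41e-13, adjusted p = 0.19 with an estimated correlation). So had 20 of 25 xenobiotic genes (median 0.32, adjusted p = 3.04e-08, adjusted p = 0.388 with an estimated correlation). Of 19 Paneth cell markers 1 was positive (median -0.44, adjusted p = 3.11e-07), of 31 ribosomal protein genes 2 (median -0.21, adjusted p = 1.65e-06) and of 25 enteroendocrine markers 5 (median -0.31, -0.29 at the bound, adjusted p = 0.000491). The other lists that passed were cholesterol and fatty acid synthesis (22 of 28 positive, adjusted p = 0.002), ethanol and aldehyde metabolism (12 of 20, adjusted p = 0.00248), and immediate early genes (1 of 18, adjusted p = 0.00567). Goblet cell markers (7 of 22, adjusted p = 0.00776), extracellular matrix (3 of 9, adjusted p = 0.0103), tight junctions (9 of 28, adjusted p = 0.0204) and small intestinal enterocyte markers (17 of 27, adjusted p = 0.0399) passed as well. For each of these 10 lists the adjusted p = 0.527 with an estimated correlation, and fry called 0 lists of all 48. In none of these 12 lists was a member called, and none passed when adjusted over the list alone. The NRF2, xenobiotic, Paneth cell, ribosomal protein, enteroendocrine and ethanol lists passed in all 8 fits that left out 1 library. Of the other 6, 3 failed without each of control libraries 1, 2 and 3 and ethanol library 2, and 2 without each of control library 4 and ethanol libraries 1 and 3 (adjusted p from 0.0585 to 0.506).

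In the fit of all organoids, the ethanol effect differed between colon and jejunum in 1267 genes (1003 with a higher fold change in colon and 264 with a lower one, 3204 genes at an unadjusted p under 0.05). This difference contains the colon effect itself, and Cldn3, for example, had one of 1.67 on the log2 scale (edgeR adjusted p = 0.00732). The same limit applies, since the simulation without an ethanol effect gave a median of 1544 such calls (1443 to 1671). limma-voom with a spread per kind of sample called 2, and the count was 4816 and 3218 without control colon libraries 1 and 2. It fell to between 724 and 825 without any 1 of control jejunum libraries 1, 2 and 4 or ethanol jejunum libraries 1, 2 and 3.

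In colon tissue (n = 4 and 4), 1 gene of 13434 was called. Rps4y2, a copy of the ribosomal protein gene Rps4x, was at 1.09 ± 0.169 CPM in ethanol and 6.85 ± 2.66 CPM in control colon, a log2 fold change of -2.62 ± 0.40 (edgeR adjusted p = 0.0371, lower in 4 of 4 ethanol libraries). Its reads may be shared with other ribosomal protein copies, the counting being unknown. The call was lost in 7 of the 8 fits that left out 1 library, and limma-voom called 0 genes and DESeq2 2. In the fit of all tissue libraries 330 genes had an unadjusted p under 0.05 where chance gives 672. With the colon tissue groups alone it was 684 of 12836 genes where chance gives 642, and 0 calls. The next smallest p-values were those of Ddx60, an interferon-induced helicase (chromosome 8, 61928087 to 62038244), at 4.93 ± 2.16 against 17.6 ± 5.55 CPM (-1.83 ± 0.35, edgeR adjusted p = 0.339). Oasl2, another interferon-induced gene, followed at 4.26 ± 0.816 against 9.49 ± 3.08 CPM (-1.16 ± 0.27, edgeR adjusted p = 1). In the other direction they belonged to Defa17, Gpr18, Scgb1b3, Eif4a3 (0.90 ± 0.26), Cyp2c40 and Sarnp (0.63 ± 0.19). Tjp1 was at 32.6 ± 8.99 against 47.4 ± 4.43 CPM (-0.54 ± 0.21, edgeR unadjusted p = 0.0193, adjusted p = 1). Ocln (-0.39 ± 0.34), Cldn3 (-0.18 ± 0.39), Lgr5 (0.58 ± 0.44), Chga (0.10 ± 0.71), Adh1 (1.44 ± 0.72), Aldh1a1 (-0.92 ± 0.64) and Muc2 (0.60 ± 0.66) had an adjusted p of 1 as well.

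As a group (adjusted p in parentheses again from camera), interferon-stimulated genes were lower in ethanol colon tissue: 26 of 27 had a negative fold change, with a median of -0.57 (camera adjusted p = 2.34e-13, adjusted p = 0.1 with an estimated correlation). No member was called over all genes, and adjusted over the list alone Oasl2 was. Ribosomal protein genes lay higher by a median of 0.31, 30 of 31 being positive (camera adjusted p = 1.83e-10, adjusted p = 0.375 with an estimated correlation). Stem cell genes (18 of 21 positive, median 0.49, adjusted p = 0.000325) and Wnt targets (12 of 16, adjusted p = 0.0213) had positive medians, each with an adjusted p = 0.375 with an estimated correlation. So had heat shock genes (14 of 15, adjusted p = 0.00263) and Paneth cell markers (13 of 18, median 0.44, 0.39 at the bound, adjusted p = 0.00464), each with an adjusted p = 0.381 with an estimated correlation, and proliferation genes (19 of 26, adjusted p = 0.0165, adjusted p = 0.796 with an estimated correlation). Among the Paneth cell markers Defa17 passed over the list alone, with 14 counts in all ethanol libraries and 1 in all controls. Some lists of the gut wall had negative medians, but smooth muscle had a positive one (0.09, camera adjusted p = 0.999) and fibroblasts did not pass (-0.16, camera adjusted p = 0.175). Those that passed were extracellular matrix (0 of 18 positive, median -0.53, adjusted p = 0.000198), adipocytes (1 of 13, median -1.27, adjusted p = 0.00116), endothelium (4 of 18, median -0.47, adjusted p = 0.00162) and neurons and glia (3 of 18, median -0.34, adjusted p = 0.0165), followed by keratins (2 of 18, adjusted p = 0.00263) and xenobiotic genes (5 of 24, adjusted p = 0.00481). For each of these 6 lists the adjusted p = 0.68 with an estimated correlation. The liver list (1 of 7, adjusted p = 0.0213, adjusted p = 0.375 with an estimated correlation) followed. Beside these stands a difference between the pieces of colon: Hoxb13, which is active in the distal colon, exceeded 5 CPM in control library 1 and ethanol libraries 1 and 2 only. Without these 3 libraries the median of the interferon list was -0.39 (22 of 27 negative), while 6 of the 14 lists lost their call (adjusted p from 0.0628 to 0.602), those of proliferation and endothelium changing direction. The interferon, ribosomal protein and stem cell lists passed in all 8 fits that left out 1 library. Of the other 11, 5, 2 and 4 failed without control libraries 1, 2 and 3, and 8, 5, 3 and 2 without ethanol libraries 1, 2, 3 and 4 (adjusted p from 0.0518 to 0.946, the highest for proliferation genes, which changed direction without ethanol library 2).

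**Figure D4:**
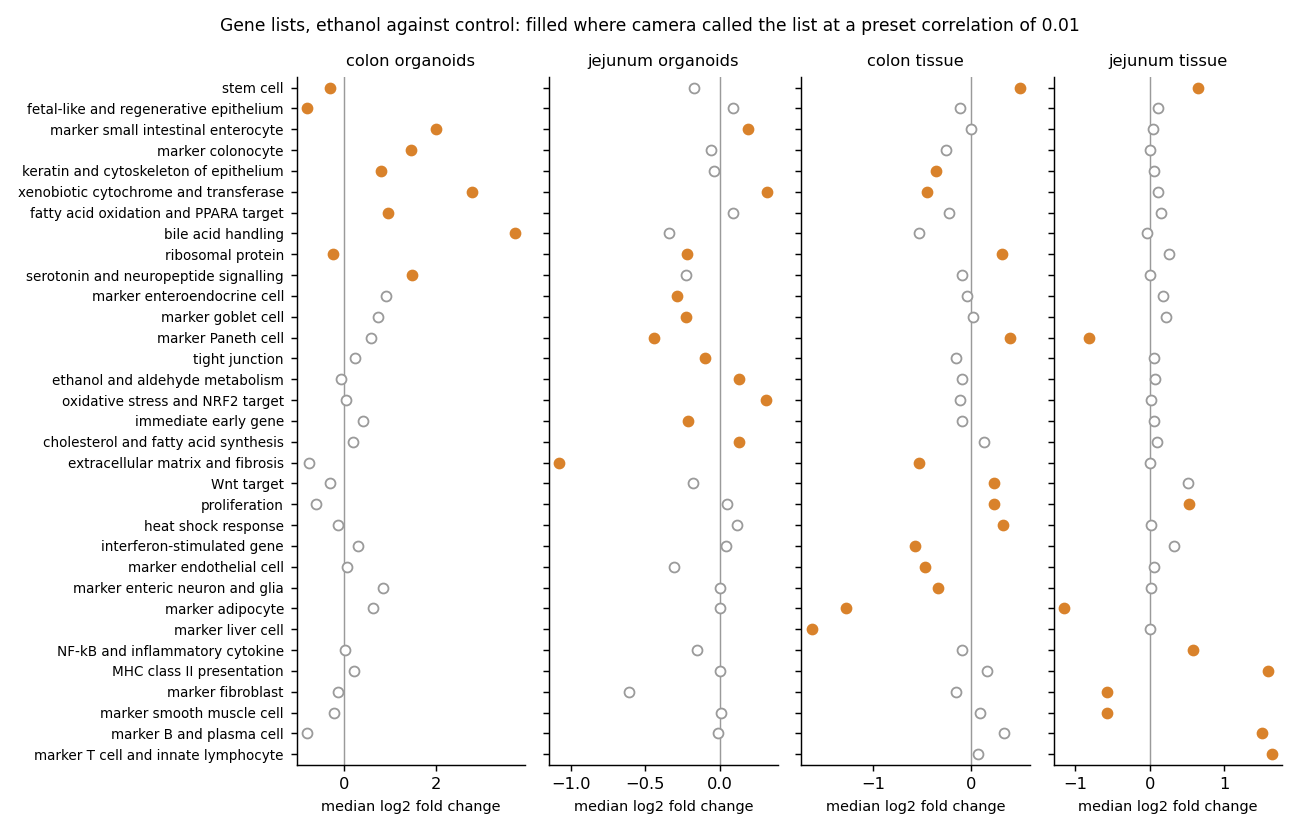
Median log2 fold change, ethanol against control, of each gene list called by camera in any of the 4 comparisons, with genes absent from a group at their bound; filled points passed camera with the preset correlation. None of them passed with an estimated correlation.

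In jejunum tissue (n = 4 ethanol and 3 control), edgeR called 0 of 13434 genes, but 1475 had an unadjusted p under 0.05 where chance gives 672, and the smallest adjusted p was 0.071. That excess was smaller in a fit of the jejunum tissue groups alone. There 616 of 10445 genes had an unadjusted p under 0.05 where chance gives 522, and 1 gene was called (edgeR adjusted p = 0.0338). limma-voom called 0 and DESeq2 31, and edgeR called 6 without control library 3 and 3 without ethanol library 1. The smallest p-values belonged to Pqlc3 (chromosome 12, 16988648 to 17000408), at 8.71 ± 1.05 against 2.21 ± 0.155 CPM (1.98 ± 0.33), and Eif2b1 (3.61 ± 0.882 against 0.139 ± 0.241 CPM), followed by Nck1, an adaptor of receptor signalling (12.5 ± 2.3 against 3.89 ± 0.973 CPM), Lins (at least 6.54-fold), Wtip (1.81 ± 0.34) and Tmem107. In the other direction the smallest belonged to Bcmo1, the enzyme that splits beta-carotene to retinal (4.6 ± 1.52 against 23 ± 6.92 CPM, -2.33 ± 0.46, edgeR adjusted p = 0.071). It was followed by Fam161a (17.9-fold lower against the floor), Zbtb3, Fzd6, Cab39l (-1.07 ± 0.26) and Col7a1 (-2.47 ± 0.60). Fam161a, Zbtb3 and Fzd6 had 11, 13 and 9 counts over all control libraries, and their group ranges were not apart. Lgr5 (0.80 ± 0.55), Tjp1 (0.02 ± 0.23), Ocln (0.27 ± 0.38), Cldn3 (0.57 ± 0.44), Adh1 (0.30 ± 0.79), Aldh1a1 (0.25 ± 0.69), Muc2 (0.58 ± 0.72) and Chga (-0.23 ± 0.79) were not called. Group ranges were apart in 7.96% of genes (chance gives 5.71%). The control libraries held 684906 to 1510057 counts outside Rn45s and the ethanol libraries 2099739 to 7606668. Together the controls had 14 counts of Pqlc3, 1 of Eif2b1, 24 of Nck1, 0 of Lins, 24 of Wtip and 5 of Tmem107. The control CPM and SD of these genes thus rest on few reads. For this comparison edgeR recovered 75% of 4-fold and 10% of 2-fold changes simulated in genes of at least 5 CPM. With DESeq2's size factors in edgeR the median log2 fold change of all genes moved by -0.12 in this comparison, and Tjp1 stood at -0.12.

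Paneth cell markers, which encode antimicrobial peptides of the crypt base, had mostly negative fold changes in ethanol jejunum tissue: 4 of 18 had a positive one, with a median of -0.82 (camera adjusted p = 3.16e-08, adjusted p = 0.0774 with an estimated correlation). Adjusted over the list alone 4 were lower and 0 higher, namely Defa24 (783 ± 121 against 1862 ± 608 CPM), Defa3, Mptx2 and Gm15284; the defensins are a family of near-identical copies among which reads may be split. Lists of lymphocytes and antigen presentation had positive medians (adjusted p from camera as above), but no member was called over all genes, and each list had an adjusted p = 0.925 with an estimated correlation. They were those of T cells (15 of 16 positive, median 1.64, adjusted p = 0.000377, Itgae and Cd8a over the list alone), MHC class II presentation (8 of 9, median 1.59, adjusted p = 0.000312, Ciita over the list alone) and B and plasma cells (10 of 10, median 1.67, 1.5 at the bound, adjusted p = 0.0031). Proliferation genes (24 of 26, median 0.52, adjusted p = 0.000377, Mcm4, Bub1 and Rrm2 over the list alone), stem cell genes (18 of 21, median 0.65, adjusted p = 0.0031) and NF-kB genes (17 of 21, median 0.76, 0.58 at the bound, adjusted p = 0.00718, Ccl28 over the list alone) were also positive. Negative medians were those of adipocyte (0 of 13 positive, median -1.15, adjusted p = 0.000294), fibroblast (5 of 20, median -0.57, adjusted p = 0.00173) and smooth muscle markers (1 of 18, median -0.57, adjusted p = 0.00558). For each of these 9 lists the adjusted p = 0.925 with an estimated correlation. In the same libraries the Rn45s share was 63.6 ± 12.3% with ethanol against 80.4 ± 4.03% in controls (two-sided exact permutation p = 0.114). With a term for that share, 5 of the 10 lists lost their call (adjusted p from 0.248 to 0.864): MHC class II, T cells, NF-kB, fibroblasts and smooth muscle, the last changing direction. The Paneth cell, MHC class II and B and plasma cell lists passed in all 7 fits that left out 1 library. Of the other 7, 2, 5 and 3 failed without control libraries 1, 2 and 3, and 2 without each of ethanol libraries 1 and 2 (adjusted p from 0.0516 to 0.377). The ethanol effect differed between colon and jejunum tissue in 0 genes with edgeR (864 at an unadjusted p under 0.05, limma-voom 0, DESeq2 2).

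Fold changes of organoids and of the tissue they model were compared over 11924 genes. Their correlation across genes was -0.0566 in colon (covariance -0.0475) and 0.00683 in jejunum (covariance 0.00303). Of the 2178 genes called in colon organoids or tissue, 46% had the same sign in both, against 48.4% of all genes. The comparisons share no library.

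The segments themselves differed far more than the treatments. Control colon organoids had more Car1 than control jejunum organoids (595 ± 9.73 against 0.216 ± 0.168 CPM, 11.33 ± 0.39, n = 2 and 4). They had more of S100a6 (4.95 ± 0.25), Anxa1 (8.00 ± 0.36), Krt7 (3.13 ± 0.20) and Cd44, the hyaluronan receptor (526 ± 24.1 against 35.9 ± 9.88 CPM). Ly6c1 and Krt4 were at least 2773-fold and 1989-fold higher. Jejunum organoids had more of the Paneth and goblet cell lectin Itln1 (at least 3383-fold), the defensin Defa21 (at least 1717-fold), Apoa4 (at least 553-fold) and Spink4 (-5.66 ± 0.35 in colon against jejunum). Of 16 fetal-like and regenerative genes 15 were higher in colon organoids and 0 lower. Lower in colon organoids were 22 of 27 enterocyte markers, 15 of 19 Paneth cell markers, 22 of 25 xenobiotic genes, 26 of 31 ribosomal protein genes and 24 of 27 genes of oxidative phosphorylation, with 0 higher in each of these lists. Adjusted over the list alone the numbers were 24, 16, 24, 26 and 24. Control tissue went the other way for ribosomal protein genes (15 of 31 higher in colon, 1 lower) and oxidative phosphorylation (9 of 27 higher, 4 lower). Goblet cell markers also differed, with 1 of 22 higher and 12 lower in colon organoids, but 12 of 23 higher and 0 lower in colon tissue. These lists therefore did not separate the segments in the same direction in both preparations. The colon organoid side rests on 2 control libraries. On the tissue side Rn45s took 76.3 to 84.3% of the counts in control jejunum and 18.3 to 24.6% in control colon. Segment and Rn45s share cannot be told apart there. In all, edgeR called 6444 genes (2994 higher in colon). limma-voom with a spread per kind of sample called 2548, and limma on the authors' values 3282.

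Colon and jejunum tissue also differed by markers of their segments. Defa24 stood at 0.182 ± 0.0973 CPM in control colon and 1862 ± 608 CPM in control jejunum (n = 4 and 3, -13.16 ± 0.55). The aminopeptidase Anpep stood at 3.79 ± 1.45 and 2450 ± 1214 CPM. Higher in colon were the posterior patterning genes Hoxb9 (chromosome 11, 96271457 to 96276595, at least 41.6-fold) and Hoxa10 (at least 53.7-fold), Sult1c2 (at least 51.9-fold), the carbonic anhydrase Car2 (372 ± 103 against 6.37 ± 6.1 CPM) and Klk1 (6.79 ± 1.06). Of 27 enterocyte markers 25 were lower in colon and 0 higher, of 18 Paneth cell markers 15 lower and 1 higher. Of 23 goblet cell markers 12 were higher and 0 lower, and of 26 colonocyte markers 13 higher and 3 lower (27, 16, 12 and 13 over the list alone in the leading direction). edgeR called 5627 genes, 3191 of them higher in colon, and limma on the authors' values called 3344. Rn45s took 18.3 to 24.6% of the counts in these colon libraries and 76.3 to 84.3% in the jejunum ones, so its share differed with the segment.

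Markers of the gut wall were lower in organoids than in tissue. In control colon the smooth muscle genes Tpm2 (chromosome 4, 43514711 to 43523765) and Myl9 were at least 2082-fold and 1365-fold lower in organoids (n = 2) than in tissue (n = 4). Of the wall markers, 18 of 18 smooth muscle, 19 of 20 fibroblast and 15 of 18 endothelial markers were lower. So were 20 of 23 goblet cell and 15 of 26 colonocyte markers, with Guca2a at 33.2 ± 9.87 against 753 ± 180 CPM and Agr2 at 5.96 ± 2.81 against 571 ± 141 CPM, and with 0 higher in each list. Higher in organoids were Wnt7b, a Wnt ligand (chromosome 15, 85535437 to 85582473, at least 2802-fold), S100a6 (7227 ± 2159 against 1428 ± 81.6 CPM), and 15 of 17 fetal-like and regenerative genes. Of 22 genes of apoptosis and p53, 15 were higher and 4 lower, the higher ones including Gdf15 (217 ± 33.2 against 1.46 ± 0.431 CPM) and Bax (48.2 ± 0.545 against 4.12 ± 1.13 CPM). edgeR called 6831 of 14785 genes (2196 higher); limma-voom with a spread per kind of sample called 2006, limma on the authors' values 2727, and a fit of these groups alone 3895.

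In control jejunum (n = 4 organoid and 3 tissue libraries), genes of protein synthesis and cell division were higher in organoids. They were 29 of 31 ribosomal protein genes (Rpl4 at 1753 ± 152 against 122 ± 44 CPM), 22 of 26 proliferation genes (Tuba1b at 149 ± 30.6 against 11.7 ± 7.82 CPM) and 19 of 23 of glycolysis and hypoxia, with 0 lower in each. Stem cell genes (16 of 23 higher, 1 lower), NRF2 targets (20 of 29 higher, 3 lower, Gstm1 at 645 ± 250 against 38.9 ± 23.5 CPM) and cholesterol synthesis (19 of 28 higher, 1 lower) went the same way. Lower were 23 of 27 enterocyte markers, among them the lactase gene Lct (3.93 ± 2.36 against 2780 ± 466 CPM), Apoa1 (-4.65 ± 0.46) and, of the colonocyte list, Krt20 (-4.32 ± 0.48). Also lower were 17 of 18 smooth muscle, 18 of 20 fibroblast, 23 of 28 interferon-stimulated, 8 of 10 MHC class II and 13 of 18 T cell genes, with 0 higher in each, and the adipocyte gene Fabp4 at least 1586-fold. edgeR called 7563 genes (3090 higher), and limma on the authors' values 3552. The tissue libraries of this comparison carried 76.3 to 84.3% Rn45s.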

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

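The tests with simulated spread, those of the interferon list and those of Rps4x and Nnt were chosen after the results they concern had been seen; the thinning test and the splits of the samples in all other comparisons were fixed before.

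The first pattern is the 2260 genes called between ethanol and control colon organoids, together with the 1267 genes whose ethanol effect was called different between colon and jejunum organoids. Counts simulated with the spread of each colon group and no ethanol effect gave medians of 2394 and 1544 such calls, so the spread within the groups may account for both numbers, although the same sets gave 0 to 1 called gene lists where 10 were measured (genes were drawn independently in them). Fewer reads in the control libraries are argued against as the source of the excess of higher genes, since after thinning to the smallest total outside Rn45s 71% of the called genes were higher (70.5 to 71.5% in 5 draws). The sets simulated without an effect had 68.4 to 75.4% higher calls (median 73.9%), against 72.5% measured, so the spread may account for this excess too. The control libraries also held fewer detected genes (9951 to 11780 against 13542 to 15383), and what lies behind that was not tested. The other splits of the 4 libraries gave 384 and 53 calls, below the 420 to 626 and 322 to 491 of the sets simulated without an effect, so these sets differ from the measured libraries there, and 3 splits are too few for a share under 0.05. An ethanol effect on single genes stays open: limma-voom with a spread per kind of sample, chosen after the data were seen, called 5 genes, among them Car1 (adjusted p = 0.0359) and Cldn7 (adjusted p = 0.0388), but was not run on the simulated sets. That model also gave control and ethanol colon organoids a common spread, although their coefficients of variation were 1.19 and 0.513.

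The second pattern is the lower level of interferon-stimulated genes in ethanol colon tissue, a median log2 fold change of -0.57 over 27 genes. A distal position, as marked by Hoxb13 above 5 CPM, is argued against as the whole cause. Without the 3 libraries with Hoxb13 the median was -0.39 (22 of 27 lower, camera adjusted p = 4e-05 at the preset correlation). With 1 more library left out the median lay between -0.50 and -0.29, at its weakest only just beyond 0.5 of the full size (-0.28). The position of the remaining pieces is not known, so differences in position among them stay open. Chance cannot be excluded, since 2 of the 35 splits of the 8 libraries, the real one included, gave a median as far from 0 (0.568, against 0.58 for the split that exchanged control library 4 and ethanol library 4). A lower interferon response in ethanol-fed mice stays a hypothesis.

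The third pattern is Rps4y2, the single gene called in colon tissue, at 3.4, 9.74, 6.51 and 7.77 CPM in the control libraries and at 0.911, 1.01, 1.15 and 1.3 CPM in the ethanol libraries; without the 3 libraries with Hoxb13 it was not called and 1 other gene was. A fall of the parent gene Rps4x, with Rps4y2 holding a fixed share of its reads, is argued against, since Rps4x had a log2 fold change of 0.18 ± 0.42. But Rps4x stood at 86.7 ± 34.6 CPM with ethanol and 76.6 ± 18.5 CPM in controls. A change in the small share of its reads counted for Rps4y2 would not show in that value. Nnt, a gene that differs between C57BL/6 substrains, had a log2 fold change of 0.20 ± 0.27. Tags near the 3' end may miss a difference elsewhere in that gene, so this value cannot decide on a substrain difference. Other genetic differences between the mice of the groups could still apply and were not tested. Rps4y2 was lower by a similar sign elsewhere without being called, at -1.40 ± 0.41 in jejunum tissue (edgeR adjusted p = 0.235), -1.06 ± 0.68 in jejunum organoids and -2.13 ± 1.06 in colon organoids, but these samples could come from the same mice, which the labels do not tell. An effect of ethanol, a substrain difference, and reads shared with Rps4x or other ribosomal copies, stay open.

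Other splits of the samples were drawn for the remaining comparisons. Chance was argued against for colon against jejunum in control tissue (1 of 35 splits as large, 5627 genes against 1247 in the highest other split). The same held for organoids against tissue in control jejunum (1 of 35, 7563 against 4069). A share of 1 of 35 is the smallest possible here, and the shares were not adjusted over the tests. Rn45s took 76.3 to 84.3% in control jejunum tissue, against 18.3 to 24.6% in control colon tissue and 19.7 to 23.4% in control jejunum organoids. These splits thus do not tell segment or preparation from the Rn45s share. Chance could not be excluded for the ethanol effect in colon tissue, where 4 of 35 splits gave at least the 1 real call and the highest other gave 31. The splits with 31, 22 and 3 calls put control library 1 and ethanol libraries 1 and 2, those with Hoxb13, on the same side, which points to a structure of the samples, although the other 2 of the 5 splits that do so gave 0 calls. In jejunum organoids and jejunum tissue 0 genes were called by the real split, so that 35 of 35 splits reached it (highest other 2 and 3). For the difference of the ethanol effect between the tissues 100 of 100 splits did (highest other 57). As many gene lists as in the real split were called in 15 of 35 splits of jejunum organoids (12 real, 21 highest other), 29 of 35 of colon tissue (14 and 25) and 5 of 35 of jejunum tissue (10 and 14), so chance could not be excluded for the number of lists. The correlation of fold changes between jejunum organoids and tissue was reached in size by 86 of 100 splits (0.00683 real, 0.0781 highest other).

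Single libraries stood apart from the rest of their group by Dixon's ratio in 9 of 115 groups of values tested, where chance gives about 6 for normally distributed values. For Tff1, Xlr3a, Defa17 and Zbtb3 the other libraries held 0. Their ratio is then 1 whatever the value, so the number given by chance does not apply to them. Control jejunum organoid library 2 had 13384 genes detected (others 13183 to 13208). Tff1 was at 0.71 CPM in control jejunum organoid library 1 and Xlr3a at 1 CPM in ethanol jejunum organoid library 2, with 0 in the others of each group. Defa17 was at 0.0809 CPM in control colon tissue library 4, with 0 in the others. Muc2 was at 7148 CPM in control colon tissue library 1 (others 4084 to 4314) and Adh1 at 612 CPM in ethanol colon tissue library 2 (69.5 to 141). In ethanol jejunum tissue, library 4 had 7.34 CPM of Tmem107 (4.67 to 4.85) and 0.156 CPM of Zbtb3 (0), and library 1 had 22.6 CPM of Cldn3 (61.8 to 68.3).

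Of the 160 genes selected in colon organoids, 104 also had a called difference of the ethanol effect between the segments, which is no separate evidence, because they were selected on the same colon libraries and sets simulated without an effect gave a median of 1544 such calls over all genes. On the log2 scale and as colon minus jejunum, the fitted difference was 10.9 for Apob (edgeR adjusted p = 0.000351), 11.2 for Fam83b (0.000241), 10.4 for Cacna2d1 (0.0027), 10.3 for Btnl1 (0.000351), 10.3 for Il22ra1 (0.0017) and 11 for Dfna5 (0.0013). It was -8.96 for Pot1b (0.0154), -11.1 for Mei1 (0.0391) and 1.67 for Cldn3 (0.00732). For all of these but Cldn3 a colon group held no count, so that the fitted value depends on the prior count and is no bound.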

How the results depend on the processing

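Of the alternatives, limma-voom with a spread per kind of sample, the left-out or modelled Hoxb13 libraries, the Rn45s term and Rn45s left out were chosen after the data were seen. DESeq2's size factors, no filter on low counts and Rn45s left out changed no count of called genes or lists by more than 1.5 times and turned no list. They moved the median log2 fold change of all genes by over 0.1 in 5 comparisons: with DESeq2's size factors by -0.12 in ethanol jejunum tissue, 0.13 for its difference from colon, 0.10 between organoids of the segments and 0.15 between colon organoids and tissue, and with Rn45s left out by 0.10 in the last and 0.20 between jejunum organoids and tissue. Where a count changed, the cause was not tested unless named.

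In colon organoids (2260 calls) limma-voom with a spread per kind of sample called 5, limma on the authors' values 1489, and the groups compared alone 0, a fit with 2 residual degrees of freedom. For the segment difference (1267) these were 2 and 678, and DESeq2 gave 2148. DESeq2 called 1 in jejunum organoids, 2 in colon tissue and 31 in jejunum tissue, and 2 for the segment difference in tissue. The 1 call in colon tissue was 0 with limma-voom, with and without a spread per kind of sample, with limma on the authors' values (which gave no value for this gene), with all 27 libraries, with the groups compared alone and with the Hoxb13 term. Without the 3 Hoxb13 libraries this call was lost too, and 1 other gene was called. In jejunum tissue the authors' values gave 3, all 27 libraries 14 and the groups alone 1; the segment difference in tissue was 1 with the authors' values. The authors' values, which cover fewer genes, gave 3282 and 3344 calls between segments in organoids and tissue, and 2727 and 3552 between preparations in colon and jejunum. A spread per kind of sample gave 2548 between organoids and 2006 between preparations in colon, where the groups alone gave 3895. An estimated correlation left 0 lists in each of the 4 ethanol comparisons, and fry called 26 in colon organoids and 0 in the other 3. Among genes with a mean of at least 10 CPM the jejunum correlation of fold changes was 0.0426.

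Leaving out 1 library gave 1504 to 5864 calls in colon organoids, 0 to 0 in jejunum organoids, 0 to 1 in colon tissue and 0 to 6 in jejunum tissue (6 without control library 3, 3 without ethanol library 1). The segment difference ranged from 724 to 4816 in organoids and 0 to 1 in tissue (1 without control jejunum library 3). Between segments it gave 5403 to 8508 in organoids and 4403 to 5645 in tissue, and between preparations 6142 to 7569 in colon and 6338 to 7190 in jejunum. Called lists numbered 2 to 14 in colon organoids (2 without control library 1), 9 to 17 in jejunum organoids, 11 to 19 in colon tissue and 7 to 12 in jejunum tissue. The correlation ran from -0.101 to -0.0135 in colon and from -0.0228 to 0.0351 in jejunum, where it turned negative without 8 of the libraries (-0.00703, -0.000347, -0.00343, -0.00152, -0.00465, -0.0228, -0.000958 and -0.00187). Where a colon organoid group kept 1 library, it was assumed to vary like the other groups.

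Some directions turned. In colon tissue the endothelial list (adjusted p = 0.602) and proliferation (0.0628) turned without the 3 Hoxb13 libraries, proliferation also without ethanol library 2 (0.946, against 1.78e-06 to 0.946 over all left-out libraries), and xenobiotic genes with the Hoxb13 term (0.97). In jejunum tissue smooth muscle turned with the Rn45s term (0.864). Of the called genes, 12, 5 and 19 turned in colon organoids without control libraries 1 and 2 and ethanol library 1, and 2 of the segment difference without control colon library 1. Without control colon organoid libraries 1 and 2, 313 and 226 turned between organoids of the segments and 258 and 224 between colon organoids and tissue. Without control jejunum tissue libraries 1, 2 and 3, 39, 61 and 112 turned between jejunum organoids and tissue, and 1 between the tissues without library 3. Under limma-voom, limma-voom with a spread per kind of sample and the authors' values, 2, 2 and 8 turned between organoids of the segments, 0, 0 and 9 between the tissues, and 21, 20 and 4 between colon organoids and tissue. Uncalled genes turned as well: with limma-voom Chga in colon organoids (0.48), Chga (-0.19) and Muc2 (-0.30) in colon tissue and Tjp1 in jejunum tissue (-0.00365). Tjp1 there also turned with DESeq2's size factors (-0.115), DESeq2 (-0.113) and the groups alone (-0.107).

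The donor numbers recur under both treatments, where they cannot be 1 mouse, and may mark the same mouse across segments and preparations, which the labels do not tell. Same-numbered control libraries deviated together with correlations from 0.026 to 0.066 between organoids of the segments, -0.083 to 0.089 between the tissues, -0.05 to -0.028 between colon organoids and tissue and -0.025 to -0.0029 between those of jejunum. Such low values do not exclude shared mice, and the tests treat the libraries as independent. Between treatments the correlations were -0.12 to 0.24 in jejunum organoids, -0.034 to 0.54 in colon tissue, 0.049 to 0.08 in jejunum tissue and 0.031 in colon organoids. In jejunum tissue all 3 pairs correlated best with their own number, as did 3 of 4 in jejunum organoids and 2 of 4 in colon tissue. In colon organoids 2 of 2 did, but with 2 libraries per group these pairs mirror each other. This is a hint from the data only. With the number as a replicate block the calls were 1184 in colon organoids, 447 for the segment difference there and 0 in colon tissue, and 6 lists were called in colon organoids. Chga (-0.0611) and Muc2 (-0.0713) in colon tissue, and Tjp1 (-0.00374) and Ocln (-0.0138) in jejunum tissue, turned under the block.

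Counts outside Rn45s were fewest in control jejunum tissue (684906 to 1510057) and control colon organoids (818240 to 2036195). For these comparisons edgeR recovered 75% and 35% of the 4-fold changes simulated in genes of at least 5 CPM. The 2 libraries per colon organoid group limit what the spread there can show.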

Other observations

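The segments also differed in transport and in cell stress genes. In control tissue (n = 4 colon and 3 jejunum libraries), 8 of 13 amino acid and peptide transporters were lower in colon and 2 higher, among the lower ones Slc7a8 (-3.88 ± 0.24) and Slc7a7 (-2.75 ± 0.22), while Slc6a14 stood at 293 ± 157 against 2.29 ± 3.6 CPM. Of 28 ion transport genes 15 were higher in colon and 6 lower: Hsd11b2, the enzyme that guards the mineralocorticoid receptor, was at 98.5 ± 25.2 against 2.11 ± 2.09 CPM, and Guca2b, which encodes uroguanylin, at 25.3 ± 7.58 against 944 ± 71.9 CPM. The claudin Cldn15 was at 160 ± 22.5 against 1510 ± 257 CPM. In these tissue libraries the Rn45s share differed with the segment, as given above. Control organoids of the segments (n = 2 and 4) showed the same signs for Slc6a14 (43.1 ± 8.93 against 0.0865 ± 0.1 CPM), Guca2b (0.317 ± 0.448 against 297 ± 113 CPM) and Cldn15 (-8.18 ± 0.44). Of the 13 amino acid and peptide transporters 6 were lower in colon organoids and 3 higher. The ion transport list did not follow the tissue, with 6 of 24 genes higher in colon organoids and 10 lower. In colon organoids 13 of 22 genes of apoptosis and p53 were higher and 1 lower, with Trp53inp1 at 142 ± 50.7 against 14.3 ± 4.25 CPM, and 15 of 20 genes of ethanol and aldehyde metabolism were lower and 2 higher, with the catalase gene Cat at 68.9 ± 12.3 against 260 ± 28.2 CPM. Neither list leaned this way in tissue. There 4 of 21 apoptosis genes were higher in colon and 7 lower, and 7 of 20 ethanol genes were higher and 5 lower.

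Organoids and tissue differed in further cell types and programmes. Tuft cell markers were lower in organoids, 8 of 14 in colon (1 higher) and 7 of 14 in jejunum (0 higher), and of 21 macrophage and dendritic cell markers 11 were lower in colon (1 higher) and 14 in jejunum (0 higher). Neuropeptide genes were lower in colon organoids in 12 of 16 cases, Sst at least 198-fold and Penk at least 123-fold (n = 2 and 4). The peptide transporter Slc15a1 was at 2.86 ± 0.512 CPM in jejunum organoids and 1417 ± 570 CPM in jejunum tissue (n = 4 and 3). Of 27 nuclear genes of oxidative phosphorylation, 20 were lower and 0 higher in colon organoids, and 17 were higher and 3 lower in jejunum organoids, a contrast that was not tested as such. Of 19 immediate early genes 12 were lower in jejunum organoids, among them Zfp36 (-4.15 ± 0.35), and 1, Myc, was higher (27.5 ± 2.49 against 1.57 ± 1.48 CPM). All calls given here are edgeR's over all genes tested.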
